A study of Mus musculus with 12 samples.

How the data were processed

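Gene-level read counts were measured in 12 libraries of mouse oesophageal epithelium, 3 in each of 4 genotype groups, taken at 6 weeks of age. Per the submitters' processing notes, reads were trimmed with cutadapt, aligned to mm10 with STAR and counted with HTSeq, and the deposited count files hold those read counts per gene symbol with no further scaling. The notes also name DESeq2, and its output is not used here. Each file lists 23337 symbols. Strand of the library preparation is not stated, so counts of overlapping genes on opposite strands, like those of near-identical gene copies, may be misplaced. Positions come from GENCODE M21, which gave 1 position for 22826 symbols.

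Pairs of libraries within each group were checked for copies on genes with at least 20 counts over the pair. The closest such pair, active IKKβ replicates 2 and 3, differed by a chi-square of 26.1 per degree of freedom, so no library repeats another of its group. Pairs across groups were not checked. Sex was read from Xist and Y-linked genes. Depth per library is given with the samples, and the shallowest library is the second of the combined group.

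Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. The filterByExpr rule at its default settings kept 14134 genes. Libraries were scaled with TMM factors, and 1 quasi-likelihood model with robust estimation was fitted to all 4 groups (common dispersion 0.0878, median prior degrees of freedom 3.04). A gene was called changed at a Benjamini-Hochberg adjusted p below 0.05. Of the 6 comparisons 5 were differences between groups, and the last was the interaction of the 2 genotype changes. Standard errors are those of the log2 fold changes in that fit, and log2 values used a prior count of 2. A gene did not overlap when all 3 libraries of a group lay above all 3 of the other, which 10% of genes meet by chance. Exact permutation tests rearranged libraries between the groups compared, or within each IKKβ background for scores, and 3 against 3 allows no p below 0.1. Where a group held 1 to 3 counts in total, the ratio of library-scaled counts is given with its exact 95% counting interval.

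The comparisons, 38 gene lists and the rule for naming genes were written before the data were examined. Genes were named if they were the 10 highest and 10 lowest log2 fold changes among called genes, or 5 and 5 against Stat3 loss and in the interaction. These had to have an average log2 CPM of at least 1 and groups that did not overlap, and predicted models, immunoglobulin, T cell receptor, sex-linked and haemoglobin genes were left out. The rule adds up to 4 members of each list with the smallest adjusted p, and always Stat3, Ikbkb, Nfkbia, Tnfaip3, Nfkb2, Socs3, Bcl3, Il6, Tnf, Il1b, Cxcl1, Krt5, Krt14, Krt4 and Krt13. Il6, with 3 counts in Stat3 loss replicate 2 and 0 elsewhere, and Il1b, with 0 to 10 counts per library, did not pass the filter. Genes called in sets of 5 or fewer are named as well, and genes named in the closing section were chosen after their values were seen. Of 865 list memberships 837 were found in the files, 17 of them under an older symbol, and 28 were not found. The 33 lists with at least 5 tested genes were tested with camera at an inter-gene correlation of 0.01, with an estimated correlation as an alternative, and with fry. Dividing the cell cycle list into 18 replication and 24 mitosis genes was done after seeing the data. The S phase and mitosis genes outside that list were likewise not among the 38 lists. List-test p values of these added sets were adjusted over the added sets alone, not the 33 lists tested. Chance levels for changes shared by 2 comparisons came from 30 simulations without effects and from the product of both call counts over the genes tested. Added after seeing the data, 30 simulations with both genotype effects and no interaction show what choosing genes by their rise does to the interaction. Genes varied independently in all of these simulations.

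The pipeline was tested on simulated data of 13974 genes with known changes. It called 28.4% of 67 genes changed by 2-fold, 74.2% of 66 changed by 4-fold and 90.8% of 65 changed by 8-fold for active IKKβ against Control. For Stat3 loss against Control these shares were 40.3% of 67, 76.1% of 67 and 92.3% of 65. In the combined group against Control they were 43.3% of 134, 76.7% of 133 and 95.4% of 130, against active IKKβ 35.8% of 67, 70.1% of 67 and 87.7% of 65, and against Stat3 loss 37.3% of 67, 75.8% of 66 and 90.8% of 65. Between 3 and 9 unchanged genes were called per comparison, and 0 of 13974 in the interaction, where none was changed. Of 100 unchanged simulated lists 0 were called. Simulated genes varied independently, so this does not show how the list test behaves on lists whose members vary together.

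Alternatives written in advance were DESeq2 size factors, library totals, no count filter, a filter of 1 CPM in 3 libraries, the DESeq2 1.42.0 Wald test, a fit without robust estimation, a sex term, each library left out in turn, a fit of only the 6 libraries compared, and a fold of at least 2. Added after seeing the data were 1 surrogate variable (sva 3.50.0), omission of both libraries rich in gastric transcripts, and the Krt4 and Krt13 share or a score of circadian genes as a covariate. Principal components used the 2000 most variable genes, and the leading pair held 26.7 and 23.7% of the variance. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 made the remaining tables and plots.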

Results

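RNA was counted in oesophageal epithelium of 6-week-old C57BL/6 mice in 4 genotype groups of 3 libraries each. The active IKKβ group carried a constitutively active IKK2 from the Rosa26 locus, switched on by a Cre driven by the ED/L2 promoter. The Stat3 loss group carried the same Cre and floxed Stat3, and the combined group carried the Cre with both alleles. Control animals carried the silent IKK2 allele and floxed Stat3 without Cre, so Cre itself differs between Control and each other group but not between the combined group and either single change. Labels do not say that the 3 libraries of a group come from separate animals, so every p-value here measures the spread between these libraries. Errors are standard errors of log2 fold changes or standard deviations between libraries, n = 3 per group, and intervals in brackets beside count ratios cover counting error only.

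In replicate order, libraries held 16.3 M, 17.9 M and 30.2 M counts in Control, 19.0 M, 24.1 M and 25.6 M with active IKKβ, 19.8 M, 21.1 M and 19.4 M with Stat3 loss, and 21.4 M, 14.8 M and 21 M in the combined group. Sex-linked transcripts were female in replicate 1 and male in replicates 2 and 3 of every group. Krt4 and Krt13, the keratin pair of the suprabasal oesophagus, together took 5.23, 6.22 and 13.9% of counts in the Control libraries. Their share was 5.06, 13.8 and 12.8% with active IKKβ, 6.01, 6.62 and 10.4% with Stat3 loss, and 11.6, 4.05 and 13.4% in the combined group. Transcripts of other tissues also varied by library. Gastric genes had a mean of 7.26 in log2 CPM (counts scaled to a library of 1 M) in active IKKβ replicate 1 and 4.58 in Stat3 loss replicate 3, against at most 1.19 elsewhere. Skeletal muscle genes stood at 6.16 in Stat3 loss replicate 3, 5.31 in active IKKβ replicate 1 and 5.05 in Stat3 loss replicate 2. Adipocyte genes reached 4.0 in Control replicate 2, and nerve genes 3.97 in Control replicate 3.

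**Figure D1:**
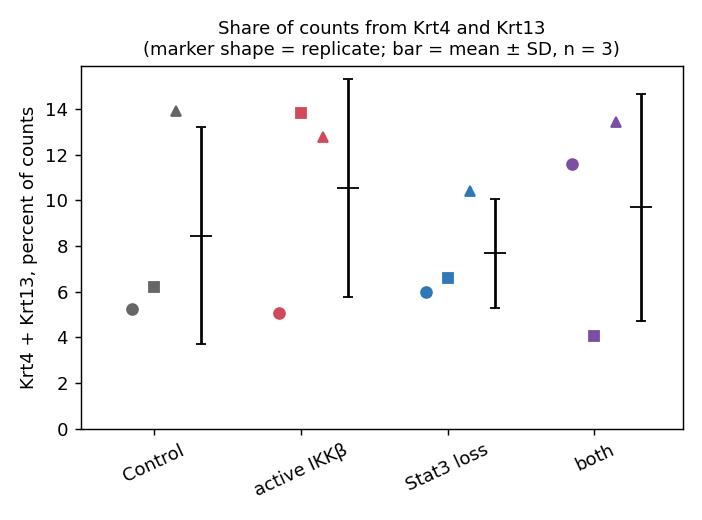
Krt4 plus Krt13 as a percentage of all counts of a library (y axis), from 4.05 to 13.9, for the 4 groups (x axis). Each point is 1 library, its marker giving the replicate number, and bars are group means ± standard deviation, n = 3.

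The targeted genes came first. Stat3 (chromosome 11, 100885098 to 100939540, minus strand, mm10), the transcription factor downstream of IL-6 family cytokines, remained well counted where it was floxed and Cre was present. Its CPM values were 174, 157 and 179 in Control, 158, 222 and 239 with active IKKβ, 139, 154 and 145 with Stat3 loss, and 170, 154 and 194 in the combined group. The log2 fold change was -0.22 ± 0.15 with Stat3 loss (edgeR adjusted p = 0.788, exact permutation p = 0.1) and 0.02 in the combined group against Control (edgeR adjusted p = 0.988). Counts per gene cannot show whether the floxed exons were missing from these transcripts. Ikbkb (chromosome 8, 22659212 to 22706589, minus strand, mm10), which encodes IKKβ, had 82.6, 60.7 and 59.7 CPM in Control and 97.7, 84.6 and 94.1 with active IKKβ. It had 72.4, 68.3 and 61.2 with Stat3 loss and 89.8, 83.4 and 97.0 in the combined group. All 6 libraries with the active allele and Cre lay above the 6 without this pair, but the gene did not pass: 0.45 ± 0.14 for active IKKβ against Control (edgeR adjusted p = 0.206) and 0.42 for the combined group against Stat3 loss (edgeR adjusted p = 0.319). With 3 libraries against 3 an exact permutation p cannot fall below 0.1, its value in both of these contrasts.

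**Figure D2:**
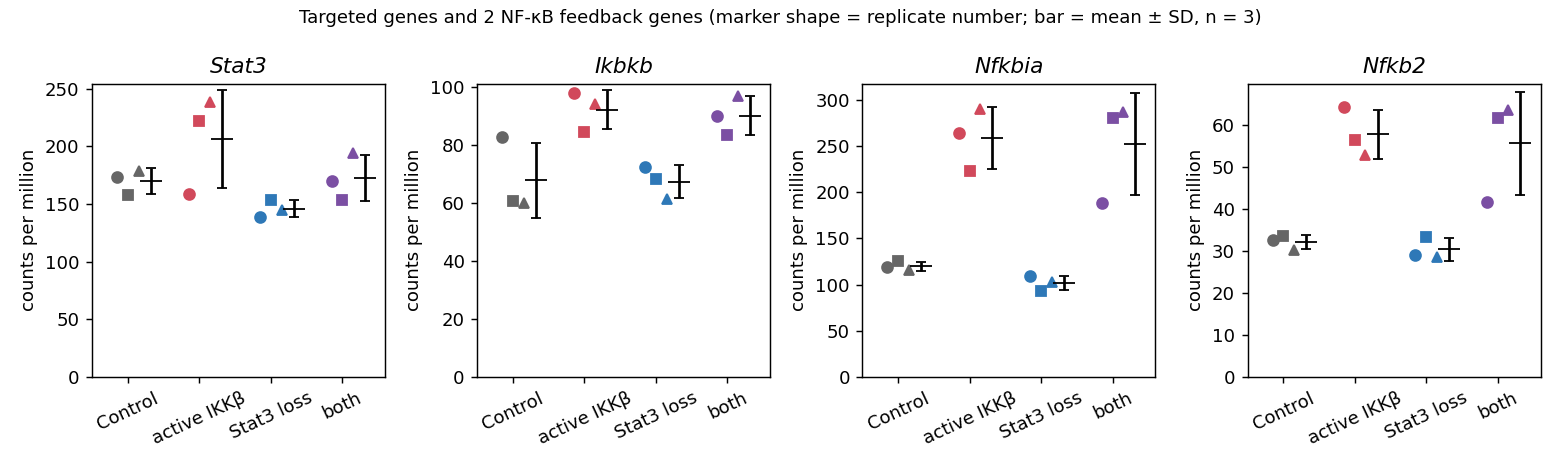
CPM (y axis) of Stat3, Ikbkb, Nfkbia and Nfkb2 in the 4 groups (x axis, the combined group marked both). Points are libraries with a marker per replicate number, and bars are mean ± standard deviation, n = 3, as for Nfkbia at 120 ± 4.99 in Control and 259 ± 33.9 with active IKKβ.

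What did active IKKβ change in epithelium with intact Stat3? It raised 127 genes and lowered 8, and antimicrobial, chemokine and squamous envelope genes were among the rises. S100a8, 1 of the calprotectin subunits, went from 1.15 ± 0.232 to 126 ± 56.4 CPM (6.78 ± 0.63, edgeR adjusted p = 6.9e-04). Nfkbia, which encodes the NF-κB inhibitor IκBα and is itself induced by NF-κB, rose 2.16-fold (1.11 ± 0.17), and Steap4, a metalloreductase, rose by 3.78 ± 0.34. Krt5, Krt14, Krt4 and Krt13, the main keratins of the basal and suprabasal layers, had log2 fold changes of -0.21, -0.06, 0.38 and 0.38 and did not pass.

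Among 33 tested NF-κB targets 9 rose, 18 when adjusted over the list alone, and none fell (camera adjusted p = 1.1e-25, adjusted p = 0.0037 with an estimated correlation). Nfkb2, the precursor of p52, rose by 0.85 ± 0.16, the apoptosis inhibitor Birc3 by 1.26 ± 0.18, Tnfaip2 by 2.99 ± 0.40 and the A20-binding protein gene Tnip3 by 5.86 ± 0.66. Tnfaip3, which encodes A20, was at 1.32 ± 0.31 (edgeR adjusted p = 0.0843) and Bcl3 at 0.94 ± 0.34. Neither passed, nor did Socs3 at -0.04 or Tnf at 2.02 ± 1.30. Of 19 chemokines 3 rose, 6 when adjusted over the list alone (camera adjusted p = 3.6e-08, adjusted p = 0.096 with an estimated correlation). Cxcl5, which recruits neutrophils, had 448 counts over the group against 1 in Control (ratio 420, 75.1 to 16638). Ccl20, the Ccr6 ligand, rose by 4.38 ± 0.77 and Cxcl16 by 2.20 ± 0.27. Cxcl1 had 97 counts against 2 (ratio 45.5, 12.3 to 381) and did not pass (edgeR adjusted p = 0.0805). The TNF, IL-1 and CSF family list had no called member of 17, 3 when adjusted over the list alone, with all 17 above 0 (camera adjusted p = 1.7e-06, adjusted p = 0.014 with an estimated correlation).

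S100a8, S100a9 and Lcn2 belong to the antimicrobial, IL-17 and IL-23, and STAT3 target lists alike, so these lists share their strongest members. S100a9, the other calprotectin subunit, rose by 3.61 ± 0.66, Lcn2, a siderophore-binding lipocalin, by 5.50 ± 0.74, and the beta-defensin Defb3 by 3.79 ± 0.75. Il23a, the p19 subunit of IL-23, rose by 4.54 ± 0.51. In all, 4 of 23 antimicrobial genes rose, 7 when adjusted over the list alone (camera adjusted p = 2.9e-09, adjusted p = 0.019 with an estimated correlation). The IL-17 and IL-23 list had 6 of 18 higher, 7 when adjusted over the list alone (camera adjusted p = 1.2e-15, adjusted p = 0.0021 with an estimated correlation). STAT3 targets had 4 of 31 higher, and 9 higher and 1 lower when adjusted over the list alone (camera adjusted p = 1.4e-08, adjusted p = 0.011 with an estimated correlation).

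Squamous genes of the wounded or cornified kind rose beside these. Krt16 rose by 4.84 ± 0.65 and Krt6b by 4.47 ± 0.90, 2 of 25 wound keratins and partners, 5 when adjusted over the list alone, and all 25 were above 0 (camera adjusted p = 3.6e-07, adjusted p = 0.14 with an estimated correlation). Of 27 cornified envelope genes 2 rose, 5 when adjusted over the list alone (camera adjusted p = 8.4e-08, adjusted p = 0.35 with an estimated correlation), Sprr2d by 7.70 ± 1.07 and Sprr2b by 3.91 ± 0.68. Krt6a with Krt6b, the Sprr2 cluster, Lyz1 with Lyz2 and the MHC genes are near copies, so counts may be misplaced among them. Krt10, a keratin of keratinising layers, rose by 3.10 ± 0.47. The homeobox gene Irx4 had 511 counts against 1 (ratio 479, 85.7 to 18972) and the vanin gene Vnn3 704 against 3 (ratio 220, 75.0 to 1070). Chi3l1, a chitinase-like protein gene, rose by 6.08 ± 0.70, the protease inhibitor gene Spink12 by 6.59 ± 1.16, and Galnt6, which starts O-glycosylation, by 5.27 ± 0.61.

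Antigen presentation moved with dendritic markers. Of 11 MHC class II genes 2 rose, 10 when adjusted over the list alone, with a median of 1.91 (camera adjusted p = 2e-14, adjusted p = 0.073 with an estimated correlation). H2-DMb2, a peptide-loading chain, rose by 3.62 ± 0.62 and the class II transactivator Ciita by 2.02 ± 0.40. Itgax, encoding CD11c, rose by 2.28 ± 0.44 and Cd207, encoding langerin, by 2.52 ± 0.50, 2 of 12 dendritic and Langerhans markers, 4 when adjusted over the list alone (camera adjusted p = 7.4e-05, adjusted p = 0.23 with an estimated correlation). H2-K1, a class I heavy chain, rose by 0.84 ± 0.16, the only 1 of 19 class I genes, 8 when adjusted over the list alone (camera adjusted p = 4e-07, adjusted p = 0.11 with an estimated correlation). Il7r, the IL-7 receptor chain, rose by 3.53 ± 0.49. Casp4, an inflammatory caspase, rose by 1.84 ± 0.30.

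Markers of other cells were higher beside these. Macrophage and monocyte markers had a median of 0.39 (camera adjusted p = 0.0028, adjusted p = 0.41 with an estimated correlation, and camera adjusted p = 0.061 without Control replicate 3). T and NK markers were at 0.75 (camera adjusted p = 0.0079, adjusted p = 0.36 with an estimated correlation), skeletal muscle markers at 1.99 (camera adjusted p = 5.5e-04, adjusted p = 0.56 with an estimated correlation) and gastric markers at 8.93 (camera adjusted p = 0.026, adjusted p = 0.55 with an estimated correlation). Each of these 3 calls was lost without Control replicate 3 (camera adjusted p = 0.085, camera adjusted p = 0.13 and camera adjusted p = 0.12) or active IKKβ replicate 1 (camera adjusted p = 0.12, camera adjusted p = 0.10 and camera adjusted p = 0.89).

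Cell cycle genes lay lower as a group: all 42 were below 0, the median was -0.55, and none passed alone or over the list (camera adjusted p = 1.1e-16, adjusted p = 0.073 with an estimated correlation). Pbk, a mitotic kinase, is outside that list and fell by 1.05 ± 0.17. The other falls included the phosphatase Phospho1 (-1.65 ± 0.25), the phospholipase Plb1 (-1.16 ± 0.19), Mgst3 (-0.72 ± 0.12), Gng10 (-0.59 ± 0.10) and the neurotrophic factor Gdnf (-1.33 ± 0.26). DESeq2 called 419 genes, 319 higher and 100 lower, and the groups did not overlap in 17.6% of genes against 10% by chance. The edgeR count was 42, 55 and 52 without Control replicate 1, Control replicate 2 and active IKKβ replicate 3, and 61 in a fit of these 6 libraries alone, with 0 lower genes in each. Without Control replicate 3 it was 64 higher and 38 lower, without active IKKβ replicate 2 60 higher and 3 lower, and without both libraries rich in gastric transcripts 75 higher and 8 lower.

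What did Stat3 loss alone change? No gene passed: edgeR called 0 of 14134 genes (smallest adjusted p = 0.179), with 1060 at unadjusted p < 0.05 where 707 would be met by chance, and DESeq2 called 104, 42 higher and 62 lower. Among DNA replication genes with the smallest adjusted p were Mcm3 at -1.47 ± 0.27, Cdc45 at -1.18 ± 0.22, Mcm4 at -1.10 ± 0.19 and the polymerase clamp gene Pcna at -0.85 ± 0.15, each with edgeR adjusted p = 0.211 and each called by DESeq2. NF-κB targets had a median of -0.05 (camera adjusted p = 0.93), and the median of STAT3 targets was -0.02 (camera adjusted p = 0.56).

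DESeq2 called the replication genes named above, but in edgeR none of the 42 cell cycle genes passed. Their median was -0.0038 and their mean -0.30, with the list test pointing down (camera adjusted p = 2.6e-07, adjusted p = 0.72 with an estimated correlation). Over the list alone 16 were lower and 1 higher. Divided by function after these values were seen, the 18 genes of DNA replication had a median of -1.04, with 17 lower when adjusted over the list alone (adjusted p = 0.010 with an estimated correlation). The 24 genes of G2 and mitosis had a median of 0.27, with library means that overlapped those of Control (camera adjusted p = 8.4e-05, adjusted p = 0.42 with an estimated correlation). Basal layer genes had a median of 0.31 with 3 of 19 higher over the list alone (camera adjusted p = 7.6e-05, adjusted p = 0.72 with an estimated correlation, and 0.071 without Control replicate 3). Among single genes near this group Dst, a hemidesmosomal linker, was at 0.90 ± 0.23, the laminin chain gene Lama3 at 0.59 and the growth factor receptor gene Egfr at 0.45, and none passed.

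Transcripts of other tissues and cells differed as well. The 8 adipocyte genes had a median of -5.46, with 6 lower over the list alone (camera adjusted p = 8.8e-06, adjusted p = 0.72 with an estimated correlation). Cfd, the adipocyte protease adipsin, was at -6.13 and the fatty acid carrier gene Fabp4 at -2.17, both called by DESeq2. These were the genes abundant in Control replicate 2. Skeletal muscle genes were at a median of 2.68 (camera adjusted p = 1.4e-07, adjusted p = 0.72 with an estimated correlation), with their highest scores in Stat3 loss replicates 2 and 3. Gastric markers were at 5.64 (camera adjusted p = 0.017, adjusted p = 0.72 with an estimated correlation), a call lost without Control replicate 1 (camera adjusted p = 0.063), Control replicate 3 (camera adjusted p = 0.071) or Stat3 loss replicate 3 (camera adjusted p = 0.36). Smooth muscle markers were at -0.87 (camera adjusted p = 2.6e-07), endothelial markers at -0.83 (camera adjusted p = 7.6e-05) and nerve markers at -1.44 (camera adjusted p = 0.0034), each with adjusted p = 0.72 with an estimated correlation. The endothelial call was lost without Control replicate 2 (camera adjusted p = 0.075) and the nerve call without Control replicate 3 (camera adjusted p = 0.47). T and NK markers were at -0.59 (camera adjusted p = 0.017) and MHC class II genes at -0.51 (camera adjusted p = 0.0086), again with adjusted p = 0.72 with an estimated correlation. Both calls were lost without Control replicate 2 (camera adjusted p = 0.31 and camera adjusted p = 0.25) or Stat3 loss replicate 3 (camera adjusted p = 0.15 and camera adjusted p = 0.28). The groups did not overlap in 13.1% of genes against 10% by chance. Leaving out Control replicate 1 gave 1 called gene, Scd1, and leaving out Control replicate 3 gave Lig1.

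What did both changes together do against Control? They raised 80 genes and lowered 45, and 12 of the falls were DNA replication genes of the fixed cell cycle list. Nfkbia rose 2.10-fold (1.07 ± 0.16, edgeR adjusted p = 0.013), Il23a by 4.84 ± 0.52 and Ccl20 by 6.51 ± 0.79. Mcm3, a subunit of the replicative helicase, fell by 2.02 ± 0.28 and Mcm4 by 1.48 ± 0.19 (edgeR adjusted p = 0.0056). S100a8 rose to 21.5 CPM (4.22 ± 0.58), below its level with active IKKβ alone.

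Of 33 NF-κB targets 10 rose, 16 when adjusted over the list alone (camera adjusted p = 5.2e-25, adjusted p = 0.0059 with an estimated correlation). Tnfaip3 passed here at 1.66 ± 0.31, with Nfkb2 at 0.79 ± 0.16, Relb, the partner of p52, at 1.58 ± 0.22 and Tnip3 at 5.59 ± 0.66. Bcl3 at -0.00, Socs3 at -0.25 and Tnf at 1.81 did not pass. Among 19 chemokines 3 rose, 4 when adjusted over the list alone (camera adjusted p = 2.8e-06, adjusted p = 0.23 with an estimated correlation). Besides Ccl20 these were Cxcl16 at 2.18 and Cxcl5, with 242 counts over the group against 1 in Control (ratio 273, 48.5 to 10810). IL-17 and IL-23 genes had 5 of 18 higher, 8 when adjusted over the list alone (camera adjusted p = 4e-13, adjusted p = 0.0032 with an estimated correlation). Lcn2 rose by 3.56 ± 0.71, and with S100a8 made 2 of 23 antimicrobial genes higher, 2 also over the list alone (camera adjusted p = 0.0051, adjusted p = 0.24 with an estimated correlation). STAT3 targets had 3 of 31 higher, 3 also over the list alone, Steap4 at 3.24 ± 0.33 among them (camera adjusted p = 7.9e-04, adjusted p = 0.14 with an estimated correlation).

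Replication genes accounted for all 12 of the 42 cell cycle genes that fell. That list had 18 lower and 1 higher when adjusted over the list alone, a median of 0.07, a mean of -0.42 and a test pointing down (camera adjusted p = 1.5e-09, adjusted p = 0.23 with an estimated correlation). In the 18 replication genes the median was -1.50, with 12 lower by the main test and 18 over the list alone (adjusted p = 0.0069 with an estimated correlation, over the added sets only). Mcm2, Mcm5 and Mcm6 fell by 1.86 ± 0.26, 1.84 ± 0.25 and 1.52 ± 0.21. Cdc6, which loads the helicase, fell by 1.94 ± 0.31. Outside the list Orc1, of the origin recognition complex, fell by 2.60 ± 0.38, the uracil glycosylase gene Ung by 2.26 ± 0.30, Uhrf1, which maintains DNA methylation, by 1.89 ± 0.27, Dtl by 1.84 ± 0.22 and the chromatin assembly gene Chaf1b by 1.87 ± 0.34. Genes of G2 and mitosis had a median of 0.29 (camera adjusted p = 1.0e-04, adjusted p = 0.35 with an estimated correlation), and none passed.

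Some single genes of the epithelium rose here too. Krt16 rose by 3.36 ± 0.61, the only 1 of 25 wound keratins and partners, whose median was -0.01 (camera adjusted p = 0.072). Krt10 rose by 3.0 ± 0.46, and Krt5, Krt14, Krt4 and Krt13 were at -0.35, -0.44, 0.15 and 0.26 without passing. Irx4 had 415 counts against 1 (ratio 467, 83.4 to 18507) and Vnn3 424 against 3 (ratio 159, 54.1 to 775). Wnt10b, a Wnt ligand gene, rose by 4.62 ± 0.42, Chi3l1 by 5.45 ± 0.69, Galnt6 by 4.87 ± 0.60, Casp4 by 1.89 and Il7r by 2.42. Cyp1b1, a cytochrome P450 gene, fell by 3.35 ± 0.54 and the growth factor gene Pdgfb by 1.15 ± 0.23. Interferon-stimulated genes had no called member of 39 and a median of -0.67 (camera adjusted p = 3.5e-05, adjusted p = 0.42 with an estimated correlation). Fibroblast markers had a median of -0.90, all 20 below 0 (camera adjusted p = 1.1e-06, adjusted p = 0.42 with an estimated correlation). Adipocyte markers were at -6.52 with 6 of 8 lower over the list alone (camera adjusted p = 3.5e-05, adjusted p = 0.25 with an estimated correlation), and nerve markers at -2.09 with 5 of 8 (camera adjusted p = 3.1e-04, adjusted p = 0.24 with an estimated correlation). Smooth muscle markers were at -0.60 (camera adjusted p = 0.0069, adjusted p = 0.69 with an estimated correlation), a call lost without Control replicate 3 (camera adjusted p = 0.09) or combined replicate 1 (camera adjusted p = 0.058). Endothelial markers were at -0.38 (camera adjusted p = 0.030, adjusted p = 0.74 with an estimated correlation), lost without Control replicate 2 (camera adjusted p = 0.57) or combined replicate 1 (camera adjusted p = 0.65). Immediate early and dissociation stress genes were at 0.26 (camera adjusted p = 0.030, adjusted p = 0.74 with an estimated correlation), lost without Control replicates 1 or 2 (camera adjusted p = 0.73 and camera adjusted p = 0.068) or combined replicates 1 or 2 (camera adjusted p = 0.12 and camera adjusted p = 0.19). Class II genes had 0 of 11 called and 1 over the list alone (median 0.79, camera adjusted p = 6.8e-04, adjusted p = 0.42 with an estimated correlation), a call lost without Control replicate 3 (camera adjusted p = 0.13) or combined replicate 2 (camera adjusted p = 0.14).

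DESeq2 called 451 genes against Control, 227 higher and 224 lower, library totals in place of TMM left 42 higher and 11 lower, and 15% of genes did not overlap against 10% by chance. The edgeR count of 125 was 55, 43, 81 and 43 without Control replicate 1, Control replicate 2, combined replicate 1 and combined replicate 3, and 14 in a fit of these 6 libraries alone. Without Control replicate 3 it was 147, with 59 higher and 88 lower. With a score of clock genes as covariate, added after the data were seen, 60 genes were higher and 13 lower, with Mcm4 at -1.25 still called and Mcm3 at -1.59 not. That score was -0.48, 2.35 and -1.62 in the combined libraries and 0.30 to 2.71 elsewhere, and the labels give no harvest time.

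How did Stat3 loss alter epithelium that carried active IKKβ? This contrast has Cre on both sides, and edgeR called 0 genes (smallest adjusted p = 0.175, 1396 at unadjusted p < 0.05), while DESeq2 called 131, 52 higher and 79 lower. S100a8 stood at -2.56 ± 0.50 (edgeR adjusted p = 0.218), Lcn2 at -1.94 ± 0.60 and Ccl20 at 2.13 ± 0.59, from 2.51 to 11 CPM. Replication genes were lower again, Mcm4 at -1.16 ± 0.19, Mcm2 at -1.39 ± 0.26, Mcm3 at -1.46 and Mcm5 at -1.31. Without combined replicate 3 S100a8 was the 1 called gene, and it fell by 3.48 (edgeR adjusted p = 0.0323).

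Replication and mitosis genes parted most clearly here. The 18 replication genes had a median of -1.05, with 15 lower over the list alone (adjusted p = 0.019 with an estimated correlation, over the added sets only). All 24 mitosis genes were higher over the list alone, at a median of 0.84 (camera adjusted p = 1.2e-37, adjusted p = 0.019 with an estimated correlation, both over the added sets only). Birc5, encoding the mitotic protein survivin, was at 0.84 ± 0.24. Averaged over both IKKβ backgrounds, the mean log2 level of the replication genes was 0.97 ± 0.15 lower with Stat3 lost (-0.97) and that of the mitosis genes 0.59 ± 0.18 higher. Because these sets were divided after the values were seen, genes outside the list were scored too. These were not among the lists written in advance and come from the same libraries, so they are no independent test. Outside the list, 29 other S phase genes were at -0.63 ± 0.11 (exact permutation p = 0.005, the smallest possible of 400 arrangements) and 27 other mitosis genes at 0.47 ± 0.13 (exact permutation p = 0.02). Group means of the 24 mitosis genes were 5.11 ± 0.19 in Control, 5.37 ± 0.34 with Stat3 loss, 4.49 ± 0.36 with active IKKβ and 5.42 ± 0.35 in the combined group. Read as 1 list of 42, the median was 0.72 and the mean 0.14 (camera adjusted p = 0.017, adjusted p = 0.57 with an estimated correlation). That call was lost without active IKKβ replicate 2, active IKKβ replicate 3 or combined replicate 3 (camera adjusted p = 0.24, camera adjusted p = 0.11 and camera adjusted p = 0.19).

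**Figure D3:**
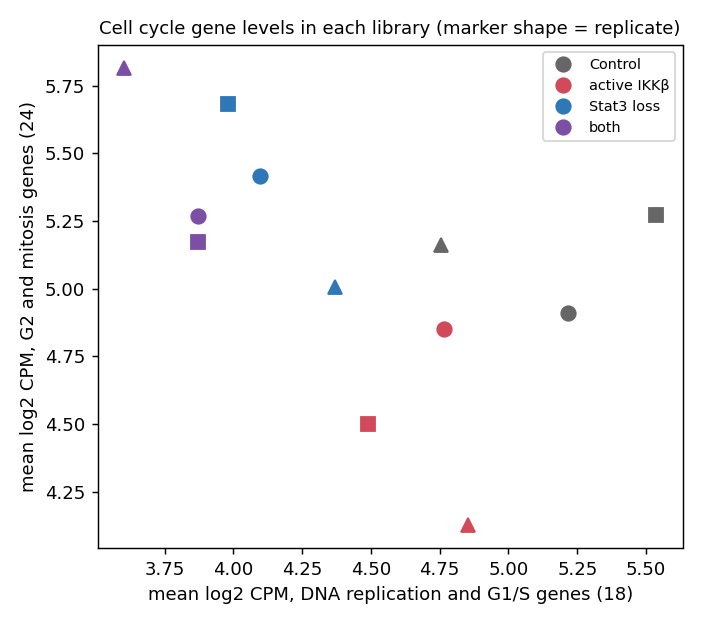
Mean log2 CPM of 18 DNA replication genes (x axis) and 24 G2 and mitosis genes (y axis), 1 point per library, colour giving the group and marker the replicate number. Replication means ran from 3.6 to 4.37 in the 6 libraries with Stat3 loss and from 4.49 to 5.54 in the other 6.

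Inflammatory, envelope and other-tissue lists pointed down. Antimicrobial genes had a median of -0.77 with 7 of 23 lower over the list alone (camera adjusted p = 5e-05, adjusted p = 0.28 with an estimated correlation), and Lyz1, a lysozyme gene, was at -4.73 from an uneven 22.3 ± 34.2 CPM. Cornified envelope genes had a median of -0.81 with 3 of 27 lower over the list alone (camera adjusted p = 9.8e-07, adjusted p = 0.39 with an estimated correlation). Sprr2d, Sprr2b and Sprr2f were at -3.07, -3.06 and -2.78. Wound keratins and partners were at -0.74 (camera adjusted p = 9.8e-05, adjusted p = 0.38 with an estimated correlation), with Krt6a at -1.42 ± 0.46. All 11 class II genes lay below 0, at a median of -0.97 (camera adjusted p = 9.8e-07, adjusted p = 0.38 with an estimated correlation), Ciita at -1.37. All 12 dendritic markers did so too, at -0.98 (camera adjusted p = 9.8e-05, adjusted p = 0.38 with an estimated correlation). Outside that list, the fractalkine receptor gene Cx3cr1, a macrophage and monocyte marker, was at -1.22. Endothelial markers had a median of -0.92, all 18 below 0 (camera adjusted p = 3.8e-06, adjusted p = 0.39 with an estimated correlation), among them Flt4, the lymphatic VEGF receptor, at -1.58. STAT3 targets had a median of -0.28 with 1 of 31 lower over the list alone (camera adjusted p = 0.0017, adjusted p = 0.28 with an estimated correlation), while NF-κB targets were at -0.10 (camera adjusted p = 0.56). The groups did not overlap in 14.7% of genes against 10% by chance.

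Markers of further cell types were lower in the same contrast. Macrophage and monocyte markers had a median of -0.32 (camera adjusted p = 0.0017, adjusted p = 0.41 with an estimated correlation, and camera adjusted p = 0.09 without combined replicate 1). T and NK markers were at -0.87 (camera adjusted p = 0.018, adjusted p = 0.46 with an estimated correlation), skeletal muscle markers at -2.22 (camera adjusted p = 5.4e-05, adjusted p = 0.46 with an estimated correlation) and gastric markers at -8.49 (camera adjusted p = 0.011, adjusted p = 0.46 with an estimated correlation). Those 3 calls were lost without active IKKβ replicate 1 (camera adjusted p = 0.37, camera adjusted p = 0.069 and camera adjusted p = 0.64), and that of T and NK markers also without combined replicate 3 (camera adjusted p = 0.051). Fibroblast markers were at -0.60 (camera adjusted p = 9.8e-05, adjusted p = 0.46 with an estimated correlation) and adipocyte markers at -4.78, with 3 of 8 lower over the list alone (camera adjusted p = 2.1e-05, adjusted p = 0.38 with an estimated correlation).

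What did active IKKβ change when Stat3 was lost? Against Stat3 loss alone the combined group had 58 genes higher and 7 lower, again with Cre on both sides. Nfkbia rose 2.48-fold (1.31 ± 0.17, edgeR adjusted p = 0.0056), Tnfaip3 by 1.69 ± 0.31 and Ccl20 by 6.35 ± 0.78. S100a8 rose by 3.46 ± 0.55 (edgeR adjusted p = 0.023). Krt5, Krt14, Krt4 and Krt13 were at -0.30, 0.11, 0.48 and 0.41 and did not pass.

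NF-κB targets had 8 of 33 higher, 17 when adjusted over the list alone, at a median of 0.87 (camera adjusted p = 8.7e-30, adjusted p = 0.0045 with an estimated correlation). Nfkb2 rose by 0.87 ± 0.16, Relb by 1.73 ± 0.23 and Tnip3 by 4.53 ± 0.60, and Bcl3 at 0.88, Tnf at 1.88 and Socs3 at -0.10 did not pass. IL-17 and IL-23 genes had 4 of 18 higher, and 6 higher and 1 lower over the list alone (camera adjusted p = 1.7e-12, adjusted p = 0.0021 with an estimated correlation), Il23a by 4.41 ± 0.50. STAT3 targets had 2 of 31 higher, S100a8 and Steap4 (3.19 ± 0.33), and 3 over the list alone (camera adjusted p = 7.1e-06, adjusted p = 0.039 with an estimated correlation). Chemokines had 3 of 19 higher, 6 over the list alone (camera adjusted p = 4.1e-10, adjusted p = 0.092 with an estimated correlation). Cxcl16 rose by 2.63 ± 0.28, and Cxcl5 had 242 counts against 2 (ratio 128, 35 to 1060). H2-K1 rose by 0.91 ± 0.16, the only 1 of 19 class I genes, 9 over the list alone (camera adjusted p = 1e-10, adjusted p = 0.074 with an estimated correlation). Class II genes had 0 of 11 called and 8 over the list alone, at a median of 1.46 (camera adjusted p = 2.3e-10, adjusted p = 0.14 with an estimated correlation).

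Markers of dendritic, T and NK cells were higher beside class II genes, while neutrophil markers pointed down (camera adjusted p = 0.049). The neutrophil call was lost without Stat3 loss replicate 3 (camera adjusted p = 0.40), combined replicate 1 (camera adjusted p = 0.086) or combined replicate 2 (camera adjusted p = 0.20). Dendritic and Langerhans markers had a median of 0.48 with 2 of 12 higher over the list alone (camera adjusted p = 0.0095, adjusted p = 0.44 with an estimated correlation). T and NK markers were at 1.25 (camera adjusted p = 0.0016, adjusted p = 0.29 with an estimated correlation), with Il7r the 1 called member. Both calls were lost without combined replicate 2 (camera adjusted p = 0.21 and camera adjusted p = 0.058), and the dendritic call also without Stat3 loss replicate 3 (camera adjusted p = 0.30). Immediate early and dissociation stress genes were at 0.66 (camera adjusted p = 7.1e-06, adjusted p = 0.32 with an estimated correlation). Skeletal muscle markers were at -2.90 (camera adjusted p = 4.8e-07, adjusted p = 0.37 with an estimated correlation) and fibroblast markers at -0.67 (camera adjusted p = 8.9e-05, adjusted p = 0.44 with an estimated correlation). Gastric markers were at -5.20 (camera adjusted p = 0.025, adjusted p = 0.53 with an estimated correlation), a call lost without Stat3 loss replicate 3 (camera adjusted p = 0.32), combined replicate 2 (camera adjusted p = 0.0504) or combined replicate 3 (camera adjusted p = 0.059).

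Among epithelial genes Krt16 rose by 4.51 ± 0.66 and Krt10 by 3.42 ± 0.47. Irx4 rose by 6.46 ± 0.66, Vnn3 by 6.03 ± 0.67, Chi3l1 by 5.37 ± 0.68, Il7r by 2.73 ± 0.50 and Casp4 by 1.73. The falls included Tns4, an adhesion protein gene (-1.01 ± 0.18), the atypical chemokine receptor gene Cxcr7 (-1.71 ± 0.31), the lipid phosphatase gene Lpin1 (-1.13 ± 0.21), the sulfotransferase gene Chst3 (-0.92 ± 0.17) and Pdgfb (-1.23 ± 0.23). Basal layer genes had a median of -0.37, 18 of 19 below 0 and none called (camera adjusted p = 1.3e-07, adjusted p = 0.19 with an estimated correlation). Interferon-stimulated genes were at -0.62, with 1 higher and 2 lower over the list alone (camera adjusted p = 2.7e-07, adjusted p = 0.29 with an estimated correlation). DESeq2 called 292 genes, 194 higher and 98 lower, library totals left 29 higher and 0 lower, and 12.9% of genes did not overlap against 10% by chance. The edgeR count of 65 was 28, 20, 32, 42 and 33 without Stat3 loss replicates 1, 2 and 3 and combined replicates 2 and 3, and 28 without both libraries rich in gastric transcripts.

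Did the effect of active IKKβ depend on Stat3? The interaction, the combined change less the sum of the single changes, was called for 0 genes (smallest edgeR adjusted p = 0.837, 658 at unadjusted p < 0.05 against 707 by chance). DESeq2 called 5, all lower: S100a8 (-3.32), Irak3 (-2.10), Kcna7 (-3.87), Lpin1 (-1.49) and Phf15 (-1.25). In edgeR S100a8 was at -3.32 ± 0.77 without passing, and Stat3 and Ikbkb were at -0.04 and -0.02. Cre enters this sum because Control lacks it.

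By gene list, 4 interaction calls held whichever single library was left out. No list was tested without both gastric-rich libraries, active IKKβ replicate 1 and Stat3 loss replicate 3. Both of their groups enter the interaction with a minus sign, so leaving out 1 kept the other. Within its group each was highest for gastric, skeletal muscle and antimicrobial genes, the last at 5.81 and 4.50 in mean log2 CPM. Antimicrobial genes had a median of -0.31, or -0.084 from summed group counts (camera adjusted p = 4.9e-04, adjusted p = 0.27 with an estimated correlation). Cell cycle genes were at 0.52 with 35 of 42 above 0 and none called over the list alone (camera adjusted p = 2.5e-11, adjusted p = 0.27 with an estimated correlation). Skeletal muscle genes were at -4.99 (camera adjusted p = 2.1e-17, adjusted p = 0.27 with an estimated correlation) and gastric genes at -13.66, or -11.21 from summed group counts with a floor of 3 (camera adjusted p = 1.8e-06, adjusted p = 0.28 with an estimated correlation).

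How much of the response to active IKKβ was shared across Stat3 backgrounds? Fold changes with intact and with lost Stat3, which share no libraries, correlated at 0.22 over all genes, against 0.0067 in simulations without a shared effect. Genes varied independently there, so 0.0067 leaves out trends that move many genes at once, as the Krt4 and Krt13 share does. Of the 127 genes raised with intact Stat3, 52 were also called higher with Stat3 lost, where 0.521 would be met by chance, and 125 had the same sign. Their median log2 fold change was 2.65 with intact Stat3 and 1.80 with Stat3 lost. Against Control both ways, 62 genes rose with active IKKβ and in the combined group, where 0.719 would be met by chance. That pair shares its 3 Control libraries, which cannot be split, so part of its correlation of 0.52 (0.50 simulated) and covariance of 0.244 (0.0946 simulated) can come from them. In the interaction 100 of the 127 genes (78.7%) were below 0, at a median of -0.59. None passed in edgeR, though DESeq2 called S100a8, 1 of the 127. Choosing genes by their rise gives part of this sign: in 30 simulations without an interaction, which called 173 genes on average, 71.1% (65.2 to 76.8%) were below 0 at a median of -0.35 (-0.53 to -0.23). None of the 30 reached the measured share or median. Simulated genes varied independently, so this range can be too narrow for genes that vary together and does not settle the question. Those simulations put the median log2 fold change at 2.32 with intact and 1.86 with lost Stat3.

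**Figure D4:**
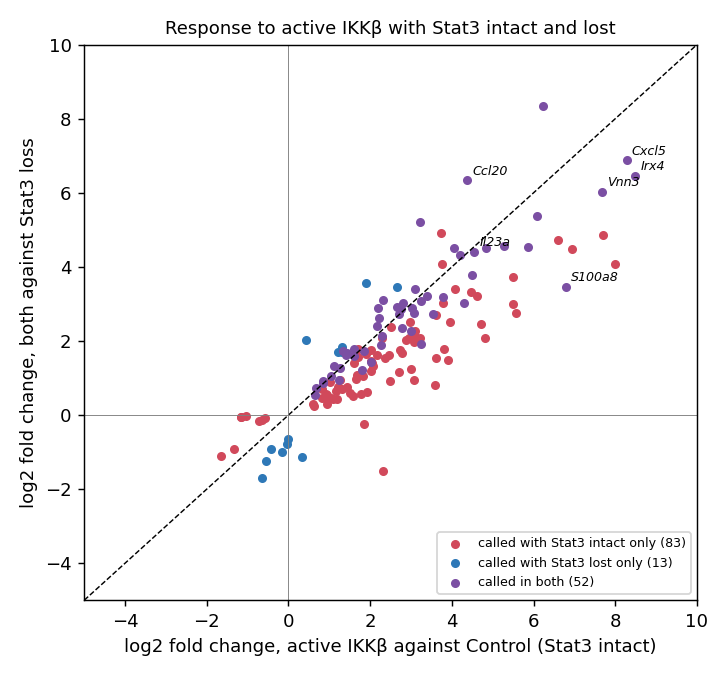
Log2 fold change of active IKKβ against Control (x axis) and of the combined group against Stat3 loss (y axis), each point 1 of 148 genes called in either, n = 3 libraries per group. Colours mark 52 genes called in both, 83 called only with intact Stat3 and 13 called only with Stat3 lost, and the dashed line marks equal change.

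Calls of the list test were many with its preset correlation of 0.01 and few with a correlation estimated from the data. Of 33 lists, 19, 12, 17, 18, 22 and 14 were called in the 6 comparisons in the order above, and 5, 0, 2, 0, 3 and 0 with the estimated correlation. Those that held were NF-κB targets and IL-17 and IL-23 genes in all 3 comparisons that add active IKKβ. STAT3 targets held with active IKKβ alone and against Stat3 loss, and antimicrobial and TNF, IL-1 and CSF family genes with active IKKβ alone. These lists share members, so they are not wholly separate findings. Besides the shared genes given above, Ccl20, Cxcl5 and Nfkbiz are in both the NF-κB and the IL-17 and IL-23 lists. Tnf, Ltb, Il1a, Il1b, Csf1, Csf2 and Csf3 are in both the NF-κB and the TNF, IL-1 and CSF family lists, and Il1b was tested in neither. Of the named genes, 12 kept their call with active IKKβ under every setting tried: Chi3l1, Cxcl16, Cxcl5, Galnt6, Il23a, Il7r, Irx4, Lcn2, S100a8, Steap4, Tnip3 and Vnn3. Galnt6, Il23a, Irx4, Steap4, Vnn3 and Wnt10b did so in the combined group against Control, and Cxcl16, Il23a, Irx4, Steap4 and Vnn3 against Stat3 loss. With 1 library left out, 12 to 23 of 38 named calls missed the threshold with active IKKβ, 4 to 13 of 35 in the combined group against Control and 4 to 18 of 24 against Stat3 loss.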

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

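The tests of fewer basal cells and fewer leukocytes were chosen only after the results were seen, as was the division of the cell cycle list.

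Each result here is a gene list whose response to active IKKβ differed with Stat3 in a test of the interaction over the list (camera adjusted p below 0.05 at the preset correlation). None of the 14 passed with an estimated correlation, the lowest value being an adjusted p of 0.27, and no single gene passed in edgeR. DESeq2 called the few genes given above, S100a8 among them (DESeq2 adjusted p = 0.020). Among inflammatory lists the median interaction was -0.21 for STAT3 targets, -0.21 for IL-17 and IL-23 genes, -0.31 for antimicrobial genes and -0.31 for interferon-stimulated genes. Neutrophil markers were at -0.49 and macrophage and monocyte markers at -0.46. Epithelial lists gave -0.22 for basal genes, -0.060 for cornified envelope genes and 0.52 for cell cycle genes. Immediate early and dissociation stress genes were at 0.28, fibroblast markers at -0.27 and smooth muscle markers at 0.38. Skeletal muscle markers were at -4.99 and gastric and glandular markers at -13.66. Computed instead from summed group counts with a floor of 3 counts over the group, the median was -0.084 for antimicrobial genes, 0.17 for cornified envelope genes and -11.21 for gastric markers, so the first is small and the sign of the next depends on the calculation. Only the antimicrobial, cell cycle, skeletal muscle and gastric calls held with every library left out in turn. That check always kept active IKKβ replicate 1 or Stat3 loss replicate 3, and no list was tested without both. Antimicrobial scores of these libraries, 5.81 and 4.50, were also the highest of their groups. Gastric scores were 7.26 in active IKKβ replicate 1 and 4.58 in Stat3 loss replicate 3, against at most 1.19 elsewhere. Muscle scores were spread more widely, at 5.31 and 4.46 in active IKKβ replicates 1 and 2, 5.05 and 6.16 in Stat3 loss replicates 2 and 3, and 3.77 in Control replicate 2.

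The cell cycle list led to its 18 DNA replication genes, lower by 0.97 ± 0.15 where Stat3 was lost (-0.97), a set picked because it was low, while 29 S phase genes outside the list were at -0.63 ± 0.11 (exact permutation p = 0.005, the smallest possible). Those 29 genes were scored in the same libraries and are no independent test. Harvest at another time of day would carry clock genes along. With the clock score as a covariate the replication difference was still -0.87, and with the Krt4 and Krt13 share it was -0.98. A straight-line trend on either score thus leaves most of the difference. Harvest time is not excluded, because 1 clock score over 12 libraries gives a rough slope (0.11 ± 0.064) and cannot tell every hour apart. Fewer basal cells would lower mitosis genes as well, and these were higher by 0.59 ± 0.18. They were divided from the low genes after the values were seen, so this rise alone cannot set fewer basal cells aside. The basal marker score, from a list written in advance, was not lower with Stat3 lost (0.11 ± 0.12, exact permutation p = 0.375). That mitosis rise came mostly with active IKKβ, from 4.49 to 5.42 in mean log2 CPM, while without it the libraries overlapped. An effect of the Stat3 genotype on replication genes, which were lower in both IKKβ backgrounds, stays open, as does harvest time.

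S100a8 belongs to the antimicrobial, STAT3 and IL-17 lists and was at 126 CPM with active IKKβ and 21.5 in the combined group (-2.56 ± 0.50). Without active IKKβ replicate 1, the library with RNA of other tissue, it was at -2.84, so that library does not make the difference. Fewer leukocytes in the sample would take neutrophil markers down with it. S100a8 lay 1.79 below the mean of the 6 neutrophil markers tested (-1.79 ± 0.98), a mean of members that split. Ltf was at -6.10 ± 2.87, Itgam at -1.43 ± 0.54 and Cxcr2 at -1.28 ± 0.84. Mxd1 was at -0.52 ± 0.41, Padi4 at 0.13 ± 0.30 and Il1r2 at 0.23 ± 0.25. Ptprc, the pan-leukocyte gene, was itself at -1.45 ± 0.54. In Control, Il1r2 was at 425 CPM, Ltf at 109, Mxd1 at 55.3, Padi4 at 13.3, Cxcr2 at 11.5 and Itgam at 4.50. Ptprc was at 2.38 CPM there, so the mean of these markers is not shown to measure leukocytes and cannot decide the question. Loss of Stat3 in keratinocytes could lower S100a8 directly, which these values neither show nor exclude.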

How the results depend on the processing

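The tests with a surrogate variable, without both libraries rich in gastric transcripts, and with the keratin share or the clock score as covariate were chosen only after the results were seen. Higher genes outnumbered lower ones under every setting in the 3 comparisons with called genes, except against Control without its replicate 3 (59 higher and 88 lower in the combined group), and counts within 1.5 times the reported value are not repeated. For active IKKβ against Control the count of 135 became 66 with library totals, 419 with DESeq2, 370 with 1 surrogate variable, 83 without both gastric-rich libraries, 399 with the Krt4 and Krt13 share as covariate and 61 with only the 6 libraries compared, and ran from 42 to 102 with a library left out. For Stat3 loss against Control 0 became 104 with DESeq2 and ran from 0 to 1 with a library left out. In the combined group against Control 125 became 53 with library totals, 451 with DESeq2, 497 with the surrogate variable, 432 with the share, 73 with the clock score and 14 with 6 libraries, and ran from 43 to 147. Against active IKKβ 0 became 131 with DESeq2, 17 with the surrogate variable and 32 with the share, and ran from 0 to 1. Against Stat3 loss 65 became 29 with library totals, 292 with DESeq2, 232 with the surrogate variable, 28 without both gastric-rich libraries, 218 with the share and 16 with 6 libraries, and ran from 20 to 81. The interaction gave 5 genes with DESeq2 and 0 otherwise. Fits of 6 and fits with a library left out hold fewer libraries, which can lower a count, but the cause was not tested for any of these changes. Without Control replicate 3 the combined count against Control rose instead, from 125 to 147. In the fit with replicate number as a block the counts were 173, 0, 125, 0, 71 and 0. Of 18 same-numbered pairs 8 correlated above 0.1 (-0.43 to 0.45), and 7 of 12 libraries matched their own number best. The median correlation was 0.065 in same-numbered pairs and -0.036 in other pairs. Replicate 1 was female in every group, so the block is partly a sex term. These values do not show that same-numbered samples were processed together. Gene lists called fell to 5, 0, 2, 0, 3 and 0 with an estimated correlation and to 11, 0, 4, 0, 5 and 0 with fry, from 19, 12, 17, 18, 22 and 14. With a library left out they ran from 16 to 23, 9 to 16, 15 to 19, 17 to 22, 18 to 22 and 9 to 19. No called named gene changed sign, and 12 of 38, 6 of 35 and 5 of 24 named calls held under every setting, the others losing theirs in at least 1. Uncalled genes near 0 did change sign for active IKKβ against Control, and the cause was not tested. Krt13 went to -0.037 with the surrogate variable and -0.13 with the clock score, and Krt4 to -0.16, -0.25 and, with the share, -0.051, and ran from -0.0077 without active IKKβ replicate 2 to 1.22. Krt14 went to 0.074 with the surrogate variable, 0.047 with the share and 0.064 with the clock score, and ran from -0.25 to 0.15 with a library left out. Socs3 went to 0.13, 0.10 and 0.29, and ran from -0.19 to 0.14 with a library left out. The replication score difference ran from -0.88 to -1.07 and the mitosis difference from 0.49 to 0.68 with a library left out, the latter 0.51 without Stat3 loss replicate 2 (exact permutation p = 0.05). Correlations between comparisons moved by less than 0.01 with DESeq2 size factors. At these depths 2-fold changes were called in 28.4 to 43.3% of simulated genes, so a gene that did not pass is not shown to be unchanged.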

Other observations

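The tests of sex, of more differentiated epithelium and of time of day at harvest, and the fit with the share as covariate, were chosen only after the results were seen.

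Within genotype groups a squamous differentiation program varied between libraries together with the Krt4 and Krt13 share. Of 14134 genes 4915 followed the share, 2620 upwards and 2295 downwards (edgeR adjusted p below 0.05). Per doubling of the share the desmosomal cadherin gene Dsg1b rose by 1.53 in log2, the serpin gene Serpinb3a by 2.02, the transglutaminase gene Tgm3 by 1.07 and the connexin gene Gjb2 by 1.42. Cornified envelope genes had a median slope of 1.29 with 26 of 27 above 0, and basal genes of -0.30 with 16 of 19 below 0. All 11 MHC class II genes had a negative slope, at a median of -0.48.

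With the share as a covariate, edgeR called 32 genes between the combined group and active IKKβ alone, where its main fit called none. DESeq2 called genes in this contrast without the share, as given above. Mcm4 fell by 1.18 ± 0.19, Mcm6 by 1.14 ± 0.18, Orc1 by 2.26 ± 0.36 and Ung by 1.83 ± 0.27. S100a9 fell by 1.72 ± 0.24, Irak3, a brake on Toll-like receptor signalling, by 1.79 ± 0.28, and the IL-22 receptor gene Il22ra1 by 0.68 ± 0.11. The fatty acid oxidation gene Eci2 rose by 0.63 ± 0.10.

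Sex of the animals alone does not set the keratin share, because in 3 of 4 groups the male libraries differed by more than 1.5-fold, though the female library was lowest in 3 of 4. Transcript length or GC content, as in degraded RNA, gave a rank correlation with the slopes of 0.21 for length and -0.07 for GC, which is too small to name and too large to set aside. More differentiated epithelium in the sample would raise the other suprabasal genes, and their median slope was 0.79 with 28 of 29 above 0. Time of day at harvest, which the labels do not give, would move clock genes with the share, and the clock score fell by 1.29 ± 0.38 per doubling (-1.29), with all 9 dusk genes below 0 at a median slope of -0.80. Epithelial composition, harvest time and RNA quality thus all stay open as candidate explanations.

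Libraries were regrouped to see how often other splits call as many genes, and 10 splits of 6 libraries are too few for a share below 0.05. Every other split also mixes both genotypes in each group. A real effect then adds to the spread within groups, so a low count in those splits does not show what chance alone would call. For active IKKβ against Control the real grouping called 135 and was the only 1 of 10 with that many, the highest other being 0. For the combined group against Stat3 loss it called 65, again 1 of 10, the highest other being 0. For Stat3 loss against Control all 10 of 10 reached the real 0, which any split must. The same held for the combined group against active IKKβ, all 10 of 10, the highest other calling 1. For the combined group against Control 2 of 10 splits reached 125. The other called 1135 and set Control replicates 1 and 2 with combined replicate 2 apart from the rest, which is the order of the Krt4 and Krt13 share and points to a structure of the samples. In the interaction 100 of 100 groupings, the real one among them, called at least the real 0, which any grouping must, and the highest other called 1041.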
